A study of Mus musculus with 2 samples.

How the data were processed

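Skin cells of mouse embryos were profiled with droplet-based 3' single-cell RNA sequencing (10x Chromium), 1 wildtype and 1 Wntless mutant library, each made from 2 to 3 pooled embryos and prepared and sequenced side by side. Tissue was dissociated with trypsin, stained with DAPI and sorted. The deposited matrices hold UMI counts (whole numbers) per gene and cell barcode, made with Cell Ranger 6.1.2 per the file headers, against genome build mm10, and the submitters also name Seurat. The deposited barcode and gene files give other information, the names of the matrix columns and of its 32285 genes. The authors also deposited a list of dermal barcodes for each library. How those cells were chosen is not stated, but each listed cell had between 1002 and 5982 genes and at most 9.83% mitochondrial UMIs. Gene coordinates (1-based, GRCm38) came from GENCODE mouse release 21, which held 32235 of the 32285 gene identifiers.

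The dermis was taken from the authors' lists, 5300 wildtype and 5028 mutant cells. Other classes came from joint clustering of all barcodes in scanpy 1.11.5: counts normalised to 10000 per cell and logged, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 0.5, without batch correction. The 28 clusters were named from marker lists fixed in advance, a name needing at least 3 markers among the 50 top genes, and low-depth, high-mitochondrial or mixed clusters were left unnamed. Epidermis was clusters 15 and 18. Doublets were scored with Scrublet per library, through scanpy. It called 4 of 8093 wildtype barcodes (0.0494%) and 169 of 7794 mutant barcodes (2.17%), and the wildtype calls are too few for a library of this size, so the caller did not work there. As an added alternative, the barcodes in the top 8% of scores were left out, 622 wildtype and 576 mutant.

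For each class, UMIs were summed over its cells in each library and divided by the class total, as CPM, with exact Poisson intervals. Ratios, always mutant over wildtype on the log2 scale, have the exact conditional binomial interval. A gene at 0 in 1 library was set against 3 counts over the class and its fold written as a lower bound. List medians hold such genes at their bound. Genes with 20 or more UMIs over both libraries counted as measured, 15609 in the dermis and 11449 in the epidermis, with a median log2 ratio of 0.03 and -0.10. Shares of cells have exact Clopper-Pearson intervals, and for a share of 0 the text gives the limit of 3 counts of the total, which is tighter than the Clopper-Pearson bound. For these shares each cell was thinned to 9000 UMIs in the dermis and 10500 in the epidermis, a planned rule based on the shallower library, and shallower cells were left out. On dermal UMI sums simulated with known folds, the intervals covered the truth for 92 to 96% of genes. The simulation drew Poisson counts, as the intervals assume, so it checks the computation and not the coverage in these data. The intervals describe counting error only. Cells are not replicates, so no p-value and no count of differing genes over the transcriptome was made.

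The 36 gene lists were fixed before the data were examined, as were the definitions of dermal condensate, Wnt-active, cycling and placode cells. They cover Wnt targets, ligands and modulators, the Hedgehog, FGF, BMP and TGF-beta pathways, dermal condensate, upper dermis, lower dermis, adipocyte, extracellular matrix, cartilage and tendon genes, placode, Eda and NF-kB, basal, suprabasal and periderm genes and epidermal signals, S phase, G2M, cell cycle inhibitor, stress, hypoxia, p53, HOX and sex-linked genes, and markers of other cell types. Each list was summarised by its members at least 1.5-fold higher or lower, its median, and the percentile of that median among 10000 random lists of the same size matched on expression in 20 bins. Named genes followed a fixed rule. In each class they were the 10 highest and 10 lowest log2 ratios among genes with 100 or more UMIs, plus up to 4 members per list with 50 or more UMIs and the largest absolute log2 ratio, plus Wls. Mitochondrial, ribosomal, haemoglobin and sex-linked genes were left out of the first part. So were genes below 5% of their level in the class with most of them, as possible free RNA. Some genes that the rule names are not reported here.

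Other settings tried were median-of-ratios scaling, scaling without the top 50 genes, means over cells, thinned cells, cells with 1000 or more genes and under 5% mitochondrial UMIs, doublet calls left out, other UMI minimums for list members, dermis-like clusters in place of the authors' lists, Leiden resolution 1.0, 1000 variable genes, epidermal cells with at most 1% collagen UMIs, and other numbers of genes for each share. Scaling alternatives moved all log2 ratios by -0.04 and 0.02 in the dermis and by 0.07 and 0.05 in the epidermis. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Raw reads were not used here.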

Results

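Single-cell RNA profiles were collected from dorsolateral and flank skin of mouse embryos at stage E14.5, when the first hair follicles form. The 2 libraries were 1 wildtype library and 1 library from littermates in which a K14Cre transgene, active in epidermal keratinocytes, had been bred to a conditional allele of Wntless (Wls). Wls carries Wnt ligands to the cell surface, so its loss from the epidermis blocks Wnt secretion there. Each library pooled 2 to 3 embryos of 1 genotype. The wildtype library held 9065 cell barcodes and 112593376 UMIs, with a median of 11341 UMIs and 3181 genes per barcode. The mutant library held 10449 barcodes and 159841679 UMIs, with a median of 14602 UMIs and 3548 genes. With 1 library per genotype, no difference below had a replicate check or a test, and all intervals are 95% intervals for counting error only.

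The first comparison asked whether the targeted gene was lower where the Cre acts. Wls (ENSMUSG00000028173, GRCm38 chromosome 3, 159839672 to 159938664) was 17.1-fold lower in the mutant epidermis, at 7.61 against 130 CPM (the gene's UMIs scaled to the class's UMI total). Those levels came from 33 UMIs in 185 mutant cells and 1083 UMIs in 525 wildtype cells of clusters 15 and 18, and the log2 ratio was -4.09 (-4.64 to -3.59). In the dermis, where the Cre is not active, Wls was at 77.0 CPM in the mutant and 91.8 CPM in the wildtype library, a log2 ratio of -0.26 (-0.31 to -0.20). The epidermal log2 ratio was -5.17 without doublet calls and -5.79 without the barcodes in the top 8% of doublet scores.

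The epidermis was compared next, to see which programmes of the Wnt-secreting layer differed when Wls was targeted there. Genes of the hair placode, the epidermal thickening that starts a follicle, were far lower in the mutant library. Of 19 measured placode genes, 16 were at least 1.5-fold lower, 1 was higher and 2 lay between, with a median log2 ratio of -2.33 (percentile 0 among 10000 expression-matched random lists). Dkk4, a Wnt-induced placode gene (chromosome 8, 22624043 to 22627547), had 2250 UMIs in wildtype and 0 in the mutant, at least 390-fold lower. Sonic hedgehog (Shh), the placode's signal to the dermis, had 373 and 0 UMIs, at least 64.6-fold lower. Fgf20, which induces the dermal condensate, had 344 and 0 UMIs, at least 59.6-fold lower. Bmp2, a BMP ligand made by placodes, was 42.0-fold lower with a log2 ratio of -5.39 (-6.85 to -4.26).

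Placode cells, defined as epidermal cells with a UMI of at least 3 of 8 core placode genes after thinning to 10500 UMIs, made up 145 of 414 wildtype cells, or 35.02% (30.4 to 39.8%, Clopper-Pearson). In the mutant library 1 of 158 cells met that definition, or 0.633% (0.0160 to 3.48%). Dermal cells, which should lack these genes, gave 0 of 3057 in wildtype and 0 of 4411 in the mutant, for which 3 counts of the total allow up to 0.0981% and 0.0680%. Wildtype macrophages gave 3 of 261 (1.15%) and wildtype mast or other myeloid cells 1 of 146 (0.685%). The mutant library gave 0 of 328 macrophages and 0 of 220 mast or other myeloid cells, which allow up to 0.915% and 1.36%, so whether the 1 mutant epidermal cell stood above background stays open. Median depths before thinning were 14715 and 22892 UMIs in the epidermis and 11154 and 15566 in the dermis.

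Several signalling pathways of the placode were lower with it. Of 14 Wnt/beta-catenin target genes, 12 were lower in the mutant epidermis and 2 lay between (median log2 ratio -1.39, percentile 0). They included Wif1, a secreted Wnt inhibitor (-4.85), Sp5, a direct target transcription factor (-4.50), Nkd1, a feedback inhibitor (-3.02), and Tcf7, a transcription factor of the pathway (-1.86). All 3 measured Hedgehog targets were lower (median -5.89, percentile 0), with the receptor gene Ptch1 at -3.28. Of 8 FGF response genes, 6 were lower (median -1.76, percentile 0), among them Etv4 at -7.63 (-12.94 to -5.14) and the ERK phosphatase gene Dusp6 at -4.99. Of 11 targets of the Eda receptor and NF-kB, a pathway that shapes placodes, 10 were lower (median -2.63, percentile 0). Edar, the receptor itself, was 15.1-fold lower, lymphotoxin beta (Ltb) was 15.5-fold lower, and the chemokine gene Cxcl10, with 53 and 0 UMIs, was at least 9.18-fold lower. Of 13 epidermal signals to the dermis, 10 were lower and 2 higher (median -1.03, percentile 0). Some genes of these lists are also on the placode list, such as Shh, Fgf20 and Bmp2 among the signals. Edar and Ltb among the Eda and NF-kB targets are too.

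Cluster 18, which held 268 wildtype cells and no mutant cell, was part of the wildtype epidermis in all these values. Within cluster 15 alone, which held cells of both libraries, the median was -0.76 for placode genes, -0.96 for Wnt targets and -5.20 for Hedgehog targets. It was -0.55 for FGF response genes (3 of 7 lower) and -0.05 for epidermal signals to the dermis (4 of 9 lower, 2 higher, percentile 56.5), and it turned to 0.30 for the Eda and NF-kB list and Ltb turned to 0.34.

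**Figure D1:**
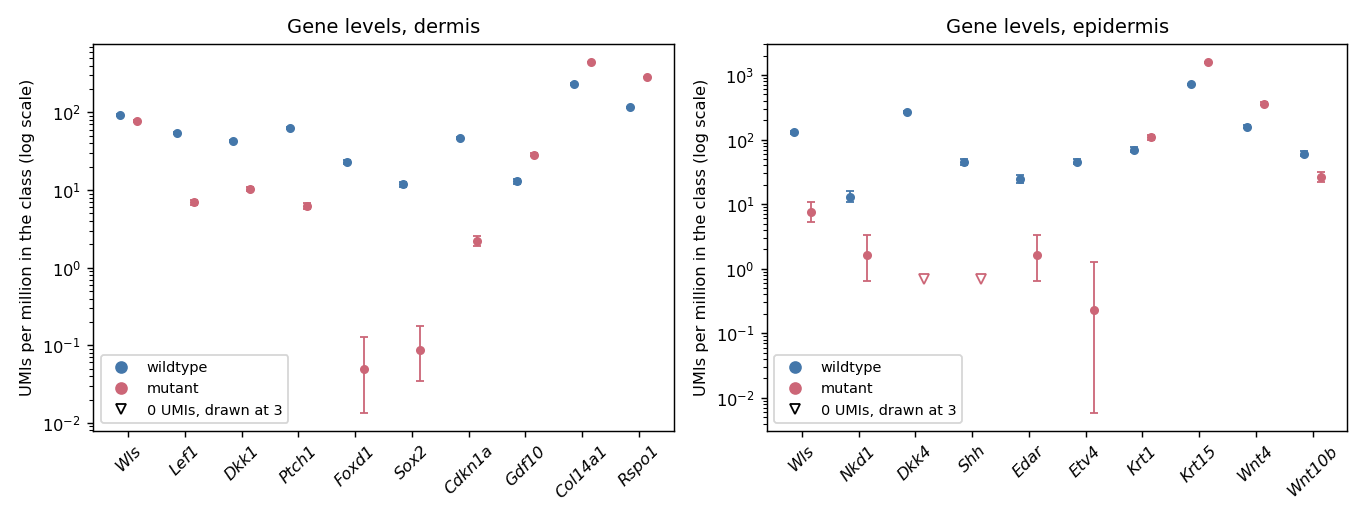
Level in CPM (log scale) of 10 genes in the dermis and 10 in the epidermis of the wildtype and the mutant library, with 95% Poisson intervals; a gene with 0 UMIs is drawn at the 3-count limit. Wls differed in the epidermis (130 and 7.61 CPM) far more than in the dermis (91.8 and 77.0 CPM). These genes were picked for the plot after their values were seen.

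Basal and suprabasal identity genes of the epidermis had medians near 0 over all epidermal cells and lower ones in cluster 15 alone. The periderm median was higher there. Of 12 basal epidermal genes, 1 was higher, 2 were lower and 9 lay between (median -0.02, percentile 82.5), and in cluster 15 alone the median was -0.34 with 2 lower and none higher (percentile 0.03). Krt15, a basal keratin, was 2.21-fold higher in the mutant library (714 to 1579 CPM), and the hemidesmosome integrin Itga6 had a log2 ratio of -0.92. Of 14 suprabasal genes, 3 were higher and 4 lower (median -0.01, percentile 80.9), with the galectin Lgals7 at -2.46 and the keratin Krt1 at 0.65. In cluster 15 alone 4 of 13 suprabasal genes were lower and none higher (median -0.47, percentile 0.01), with Krt1 at -0.20. Of 7 periderm genes, 2 were higher and 3 lower (median 0.20, percentile 92.1), among them Krt18 at -2.64 and Cldn6 at -0.80, which was 0.35 in cluster 15 alone. In that cluster 2 of 6 periderm genes were higher and 1 lower (median 0.40).

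More Wnt ligand genes were higher than lower in the mutant epidermis. Of 14 measured ligands, 7 were higher and 3 lower (median 0.60, -1.12 to 1.19, percentile 100), and in cluster 15 alone 4 of 13 were higher and 1 lower (median 0.31). Wnt4 was 2.28-fold higher and Wnt3a 2.40-fold higher, while Wnt16 had a log2 ratio of -1.12. Wnt10b, a placode ligand, had a log2 ratio of -1.20 over all epidermal cells and 0.29 in cluster 15 alone. Of 19 Wnt receptors and modulators, 5 were higher and 3 lower (median 0.23, percentile 99.8), with the Wnt agonist Rspo3 at 1.68 and its receptor Lgr4 at -1.13. BMP response genes went both ways, with 3 of 8 higher and 3 lower (median -0.24, percentile 18.8, and 0.18 in cluster 15 alone). Id3, a BMP-induced repressor, was at -1.89, and Msx2 was at -1.84 but 0.72 in cluster 15 alone. Of 6 TGF-beta response genes, 3 were lower and 3 lay between (median -0.70, percentile 1.35), with the matricellular gene Ccn2 at -3.49.

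Of the cell cycle lists in the epidermis, G2M genes were close to even, while S phase genes and cell cycle inhibitors had negative medians. Of 50 G2M genes, 1 was higher, 1 was lower and 48 lay between (median 0.09, percentile 100); the lower one was Lbr, the lamin B receptor gene, at -1.28. The median was -0.05 in thinned cells and up to 0.18 under other settings. Of 41 S phase genes, 7 were lower and 34 lay between (median -0.34, percentile 0), and in cluster 15 alone 3 were lower (median -0.26). Of 8 cell cycle inhibitors, 2 were higher and 4 lower (median -0.57, percentile 0.19), with Cdkn1a, which encodes p21, at -2.43 and Gas1 at 1.18. In cluster 15 alone 3 of 8 inhibitors were lower and none was higher (median -0.43). Of 14 dissociation stress genes, 7 were lower, 3 higher and 4 between (median -0.69, percentile 0), and of 11 hypoxia and glycolysis genes, 6 were lower and 5 between (median -0.67, percentile 0.01). Of 10 apoptosis and p53 genes, 5 were lower and 1 higher (median -0.50, percentile 0.68), with Bbc3 at -0.96. In cluster 15 alone 3 of the 10 were lower and 1 higher (median -0.13, percentile 35.4), with Bbc3 at 0.58.

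Outside the lists, the genes with the largest positive log2 ratios in the epidermis were Tmem108 (2.57), Crtac1 (2.55), Mgll, which encodes monoacylglycerol lipase (2.44), and Rtn1 (2.24). The long noncoding RNA Hotairm1 of the HoxA cluster was 3.31-fold higher, at 248 against 74.7 CPM. The other 5 of the 10 were Dipk1c, L3hypdh, Triqk, 3110099E03Rik and Nudt11, with log2 ratios from 1.76 to 1.92. Among the lowest, Cyfip2 was at -7.28 (-12.59 to -4.80), Rragd at -6.06 (-9.11 to -4.19), and Pthlh, the parathyroid hormone-related peptide, at -5.91 (-7.54 to -4.68). Mical2, at -6.06 (-11.37 to -3.55), and Kcnmb4os2, at -6.00 (-11.31 to -3.49), had 1 UMI each in the mutant library, and Gm10320, at -6.40, had 5.

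The dermis, which keeps its own Wls, was compared to ask how it differed next to an epidermis in which Wls was targeted. It was defined by the authors' lists of dermal barcodes, 5300 wildtype cells with 62876844 UMIs and 5028 mutant cells with 81179288 UMIs. Wnt/beta-catenin targets were lower in the mutant dermis. Of 15 measured targets, 11 were at least 1.5-fold lower, none was higher and 4 lay between (median log2 ratio -0.72, percentile 0). Cluster 6 held 1124 wildtype cells and no mutant cell, and 1108 of its cells were on the authors' dermal list. Without cluster 6, 7 of the 15 targets were lower and none higher (median -0.58). The same numbers held with the 6 dermal clusters shared by both libraries weighted alike (median -0.53). Lef1, the transcription factor of the pathway, was 7.83-fold lower at 6.92 against 54.2 CPM, the Wnt deacylase gene Notum was 5.10-fold lower, the secreted inhibitor Dkk1 4.13-fold lower and Tcf7 3.39-fold lower.

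Wnt-active dermal cells, those with a UMI of at least 3 of 8 target genes after thinning to 9000 UMIs, made up 42.5% of wildtype cells (40.9 to 44.0%, 1699 of 4000) and 13.3% of mutant cells (12.4 to 14.3%, 621 of 4661). Muscle cells measured the same way gave 2.87% and 0.428%, and macrophages 2.94% and 0.300%. Median depths before thinning were 17146 and 23842 UMIs in muscle cells and 16188 and 24385 in macrophages. Thinning left out 1300 wildtype and 367 mutant dermal cells that were too shallow.

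**Figure D2:**
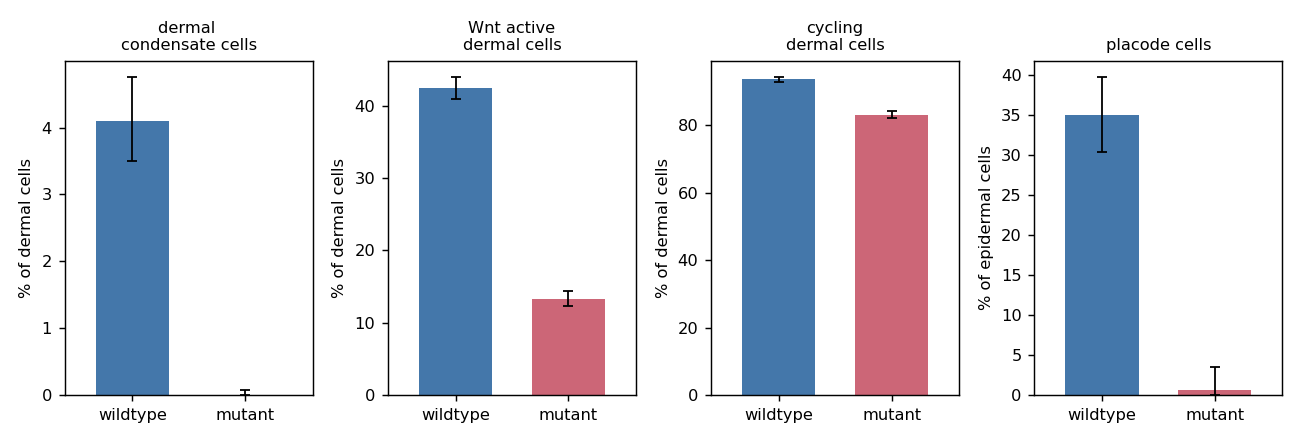
Share of cells (%) that met each definition in the wildtype and the mutant library after thinning to equal UMI totals, with 95% Clopper-Pearson intervals. Wnt-active dermal cells made up 42.5% and 13.3%, dermal condensate cells 4.10% and 0%, and placode cells 35.02% and 0.633%.

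The dermal condensate, the cluster of fibroblasts under each placode that becomes the dermal papilla, was not detected in thinned cells of the mutant library. Cells with a UMI of at least 3 of 8 core condensate genes made up 164 of 4000 wildtype dermal cells, or 4.10% (3.51 to 4.76%). There were 0 of 4661 in the mutant, for which 3 counts of the total allow a share of up to 0.0644% (the Clopper-Pearson upper bound is 0.0791%). In wildtype muscle cells the same count gave 0 of 488, and in wildtype macrophages 4 of 272, or 1.47%. Without thinning 282 of 5300 wildtype cells (5.32%) and 1 of 5028 mutant cells (0.0199%) met the definition, and with at least 2 core genes the shares were 8.22% and 0.858%. Of 22 dermal condensate genes, 12 were lower in the mutant dermis, 2 were higher and 8 lay between (median -0.61, percentile 0). The transcription factor Foxd1 (chromosome 13, 98354242 to 98359305) had 1444 and 4 UMIs, a log2 ratio of -8.86 (-10.74 to -7.50). Sox2, the transcription factor that marks the condensate, was 138-fold lower, Sox18 was 52.8-fold lower and the neuropeptide galanin (Gal) was 214-fold lower. Without cluster 6 the median of the list was 0.10 with 9 of 22 genes lower and 3 higher, and without cells that had a UMI of 2 or more core genes it was 0.06 with 8 of 21 lower and 4 higher. With the shared clusters weighted alike it was 0.0057 with 9 of 22 lower and 4 higher. Within the 6 shared clusters the median was -0.68 in cluster 1 (12 of 21 lower, 1 higher, percentile 0) and from 0.06 to 0.51 in the other 5, the highest in cluster 2 (2 of 16 lower, 5 higher, percentile 100).

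Hedgehog targets were lower in the dermis as well, and some FGF and BMP response genes were. All 4 Hedgehog targets were lower (median -3.23, percentile 0), with Ptch1 10.1-fold, the pathway's transcription factor Gli1 8.64-fold and the antagonist Hhip 3.59-fold lower. Of 8 FGF response genes, 3 were lower and 5 lay between (median -0.33, -2.27 to 0.09, percentile 0.06), namely Etv4 (-2.27), Dusp6 (-1.18) and Spry1 (-0.85), which encode an FGF-induced transcription factor and feedback inhibitors. Of 10 BMP response genes, 5 were lower and 1 higher (median -0.43, -1.03 to 0.24, percentile 0.01), among them the BMP antagonist Grem1 (-1.78), Id1 (-1.03) and Id3 (-0.75). With the shared clusters weighted alike, 3 of 8 FGF response genes (median -0.07) and 2 of 9 BMP response genes (median -0.36) were lower. TGF-beta response genes were not lower, with 2 of 8 higher and 6 between (median 0.17, percentile 88.5, and -0.0030 with the shared clusters weighted alike), and Tgfbi at 1.07.

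Genes of the upper and of the lower dermis had medians of opposite sign. Of 14 upper dermis genes, 7 were lower, 1 was higher and 6 lay between (median -0.59, percentile 0); 5 of these genes, such as Lef1 and Dkk1, are also on the Wnt target list. Trps1, a zinc finger repressor, was 5.53-fold lower, and Dpp4, a surface peptidase of fibroblast progenitors, was 2.97-fold higher. Of 16 lower dermis and fascia genes, 8 were higher and none was lower (median 0.57, percentile 100). Gdf10, a TGF-beta family ligand, was 2.20-fold higher, the homeobox gene Meox2 2.01-fold, the fibril-associated collagen gene Col14a1 1.93-fold and the microfibril gene Mfap5 1.91-fold higher. Without cluster 6 these medians were -0.32, with 5 of 14 lower, and 0.35, with 6 of 16 higher. With the shared clusters weighted alike they were -0.28, with 6 of 14 lower and 1 higher, and 0.33, with 1 of 16 higher and 1 lower.

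Lists of connective tissue lineages had positive medians in the mutant dermis, with members on both sides in the adipocyte, cartilage and tendon lists. Of 22 extracellular matrix genes, 4 were higher, none was lower and 18 lay between (median 0.45, percentile 100), but 1 was higher without cluster 6 (median 0.34) and none with the shared clusters weighted alike (median 0.19). Lox, the collagen crosslinking enzyme, was 1.81-fold higher, fibronectin (Fn1) was 1.61-fold higher, and the collagen gene Col1a1 had a log2 ratio of 0.59. Of 9 adipocyte lineage genes, 3 were higher and 1 lower (median 0.51, percentile 99.7), with the preadipocyte factor Ebf2 at 1.40 and Pparg, the master regulator of adipocytes, at 0.85; with the shared clusters weighted alike 1 was higher and 1 lower (median 0.41). Of 9 cartilage genes, 3 were higher and 2 lower (median 0.46, percentile 95.6), and of 6 tendon genes, 2 were higher and 1 lower (median 0.41, percentile 94.8), with Tnmd at 1.21 and Scx at 1.01. Over all dermal cells the cartilage and tendon medians lay within the range of the random lists, which reached 0.53 and 0.47. With the shared clusters weighted alike these medians were 0.65 (4 of 7 higher) and 0.09 (2 of 6 higher, 1 lower). Without cluster 6 they were 1.02 (4 of 7 higher) and 0.16 (2 of 6 higher, 1 lower).

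**Figure D3:**
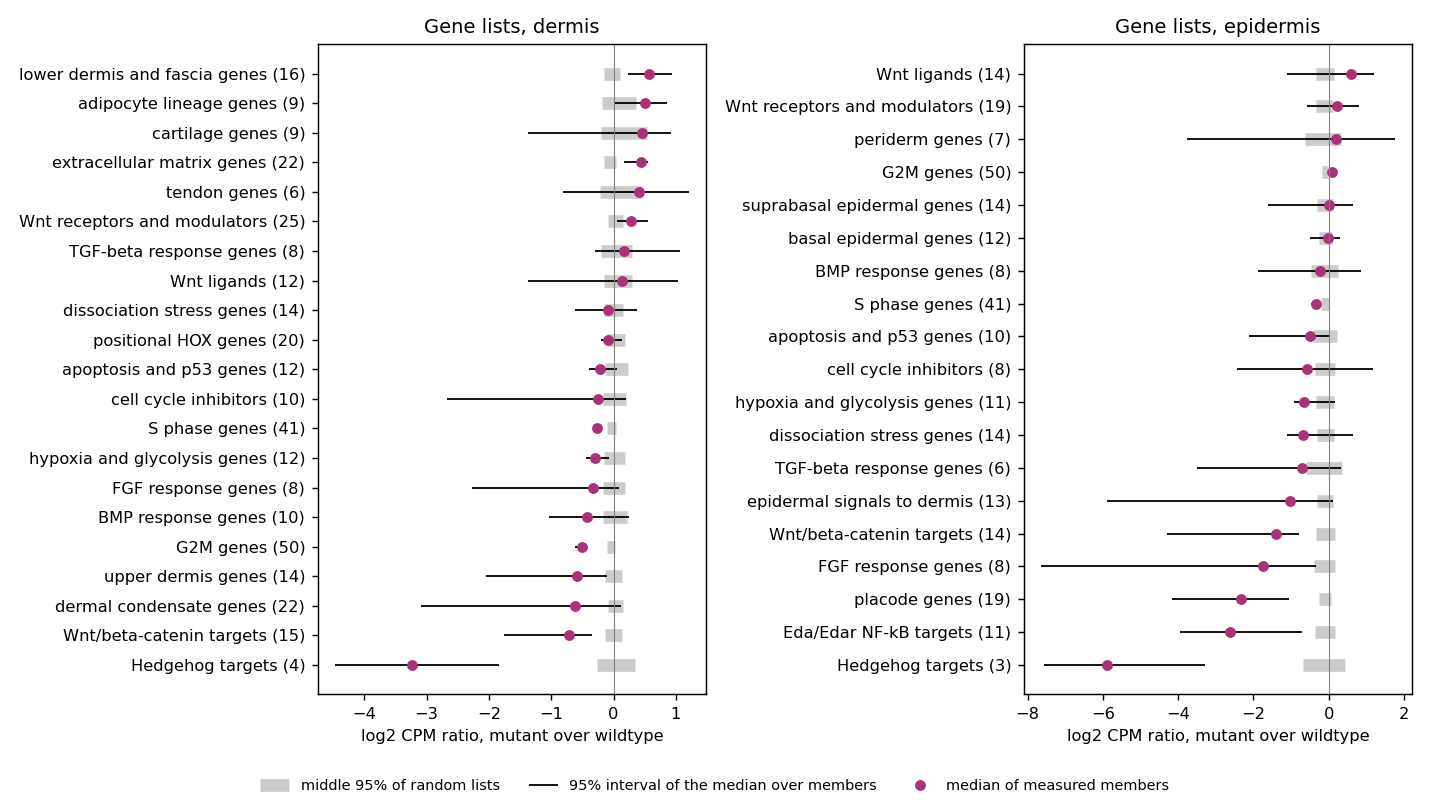
Median log2 ratio (mutant over wildtype) of each gene list in the dermis and in the epidermis. In the dermis Hedgehog targets (-3.23), Wnt targets (-0.72) and dermal condensate genes (-0.61) lay below 0 and lower dermis and fascia genes (0.57) above it; in the epidermis placode genes lay at -2.33.

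G2M genes were lower over all dermal cells of the mutant library but not with the shared clusters weighted alike. Of 50 G2M genes, 18 were at least 1.5-fold lower, none was higher and 32 lay between (median -0.51, -0.61 to -0.41, percentile 0). The number at least 1.5-fold lower was 8 in dermal fibroblast-like clusters, 36 in thinned cells and 41 without cluster 6, none being higher in these settings. With the shared clusters weighted alike it was 1 of 50 (median 0.10), and medians within these clusters ran from -0.66 in cluster 2 to 0.20 in cluster 12. Lbr was 2.01-fold lower, the mitotic kinase Aurka 1.75-fold and the ubiquitin-conjugating enzyme Ube2c 1.67-fold lower. All 41 S phase genes lay between (median -0.27, percentile 0), with the exonuclease Exo1 at -0.49. Of 10 cell cycle inhibitors, 3 were lower and 7 lay between (median -0.25, percentile 0.37), but with the shared clusters weighted alike 3 were lower and 1 higher (median -0.0011), and within each of these clusters the median was above 0 (0.0023 to 0.16). Cdkn1a, also on the condensate list, was 21.1-fold lower, Cdkn2a 6.39-fold lower, and Cdkn1c, which encodes p57, 1.43-fold higher. After thinning, UMIs of at least 5 G2M genes were found in 93.7% of wildtype (92.8 to 94.4%) and 83.1% of mutant dermal cells (82.0 to 84.2%). Muscle cells gave 94.1% and 93.6%, and macrophages 96.7% and 92.5%. Both cell types can cycle, so these shares are no background, and free RNA stays open as part of the dermal shares. With at least 10 genes the dermal shares were 58.2% and 34.1%, and in unthinned cells, which were deeper in the mutant library, they were 89.5% and 91.4%. Thinning only removes UMIs, so the lower wildtype share without it comes from 1300 shallow wildtype cells that thinning left out. In the mutant library thinning left out 367 cells.

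Dermal Wnt ligands and modulators went both ways. Of 12 ligands, 3 were higher and 3 lower (median 0.14, percentile 78.4). Wnt10a was 5.41-fold and Wnt6 3.57-fold lower, while Wnt2 was 2.06-fold higher and Wnt16, with 12 and 45 UMIs, 2.90-fold higher. Of 25 receptors and modulators, 6 were higher and 1 lower (median 0.28, percentile 99.9). R-spondins strengthen Wnt signals at the receptor, and Rspo1 was 2.46-fold higher at 286 against 116 CPM, while Rspo2 was 8.26-fold higher from 6 and 64 UMIs. The Wnt receptor gene Fzd6 was 2.22-fold higher, and Frzb, a secreted Wnt inhibitor, was 5.79-fold lower.

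The dermal gene with the highest log2 ratio was Lefty1, a secreted Nodal inhibitor (chromosome 1, 180935022 to 180938400), with 1 wildtype and 835 mutant UMIs, a log2 ratio of 9.34 (6.86 to 14.64). Gm10503 was at 7.53 (5.04 to 12.84), with 0 wildtype UMIs and 9 to 54 mutant UMIs in each of the 6 other classes compared, and Gm35082, with 0 and 110 UMIs, was at least 28.4-fold higher. The oncostatin M receptor Osmr (3.23), the channel gene Trpc5 (3.17), Wfdc18 (3.15), A730046J19Rik (3.13), the chemokine Cxcl13 (2.39), Gm26871 (2.33) and Tbc1d8b (2.32, and 1.14 to 2.82 in the same 6 classes) made up the rest of the 10. Besides the condensate genes, the lowest included Gm11541 (-8.06, -13.37 to -5.57), Ly6d (-7.39, -10.44 to -5.52), Gm10320 (-7.04), the Notch ligand Dll1 (-5.73), and Trdc, with 134 and 0 UMIs, at least 57.7-fold lower.

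Stress genes in the dermis had a median near 0 over all cells and lower ones within clusters. Of 14 dissociation stress genes, 3 were lower and 1 higher (median -0.09, percentile 15.2). Within each of the 6 dermal clusters with cells of both libraries the median of this list lay between -0.69 and -0.19 (percentiles 0 to 0.02). Of 12 hypoxia and glycolysis genes, 1 was lower (median -0.30, percentile 0.01). Of 12 apoptosis and p53 genes, 2 were lower (median -0.22, percentile 0.21), with the growth arrest gene Gadd45a 3.46-fold lower. Of 20 positional HOX and related genes, 2 were lower and 1 higher (median -0.09, percentile 3.4), with Hoxd9 at -0.72.

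Markers of other cell types were also measured in each class, where free RNA, doublets and expression by the class itself were not separated. In the dermis, 3 of 5 erythroid markers were higher in the mutant library (median 1.14, percentile 100), with the globin gene Hbb-bs 3.28-fold higher, but with the shared clusters weighted alike 2 were higher and 1 lower (median 0.11). Within these clusters their median was at least 0.59 in 5 and -0.58 in cluster 12. In the dermis keratin markers were lower (5 of 8, 1 higher, median -1.03, percentile 0), with Krt14 7.37-fold lower. Dermal medians were -0.02 for 7 endothelial markers (2 higher), 0.15 for 7 macrophage markers (1 lower), 0.27 for 7 mural markers (1 higher, 1 lower) and 0.09 for 5 Schwann and melanocyte markers (1 higher). The 6 muscle markers had 3 lower and 1 higher (median -0.65), which turned to 0.24 for members with 100 or more UMIs. In the epidermis, fibroblast markers had a median of -0.13 (2 of 8 lower), erythroid markers -0.08 (all 5 between), Schwann and melanocyte markers -0.27 (1 of 5 higher, 1 lower), and the 2 endothelial markers -0.16. The 3 macrophage markers were lower (median -2.83). Of 3 muscle markers in the epidermis, 2 were higher (median 1.17); Actc1, at 2.37 from 19 and 51 UMIs, was -3.15 without doublet calls.

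Cell classes were compared last, as shares of all barcodes. Cells on the authors' dermal lists made up 58.5% of the wildtype library (57.4 to 59.5%) and 48.1% of the mutant library (47.2 to 49.1%), and erythroid cells 6.76% (6.25 to 7.30%) and 13.4% (12.8 to 14.1%). Among cells with at least 1000 genes and under 5% mitochondrial UMIs, the dermal share was 0.49 points higher in the mutant library and the erythroid share 0.52 points higher. Barcodes with over 10% mitochondrial UMIs made up 1.62% of the wildtype and 11.3% of the mutant library. Shares of muscle cells (5.77% and 4.60%), macrophages (3.42% and 3.61%), mural cells (2.74% and 2.36%), Schwann or neural crest cells (2.72% and 2.68%), mast or other myeloid cells (1.72% and 2.24%), endothelium (0.739% and 0.775%), lymphatic endothelium (0.188% and 0.316%) and melanocytes (0.408% and 0.450%) lay closer together in points. By ratio, lymphatic endothelium, mast or other myeloid cells and muscle cells differed more than the dermal share did. The muscle intervals (5.30 to 6.27% and 4.21 to 5.02%) did not overlap, but these are shares of all barcodes. The totals included 129 wildtype and 1069 mutant barcodes of cluster 4, with a median of 73.0% mitochondrial UMIs. They also included 613 wildtype and 1400 mutant erythroid cells. Muscle shares without these barcodes were not computed, so a muscle difference cannot be read from them. Epidermal cells made up 5.79% (5.32 to 6.29%) and 1.77% (1.53 to 2.04%), and this share is no measure of the tissue, since cluster 18 was defined by genes that differed between the libraries.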

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

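No test was run for this part, so the differences between dermis and epidermis given here were not tested. Wnt10a, a Wnt ligand of placodes, had a log2 ratio of 0.74 in the epidermis and -2.43 in the dermis, opposite directions in the 2 tissues. Wnt16 had a log2 ratio of -1.12 in the epidermis and 1.54 in the dermis. Barcodes in clusters that the naming rule left unnamed made up 16.2% of the mutant library (15.5 to 16.9%) and 7.79% of the wildtype library (7.24 to 8.36%). Some of them the authors listed as dermal (66 in cluster 7, 1 in cluster 22 and 3 in cluster 26 over both libraries). Among the unnamed clusters, cluster 4 held 129 wildtype and 1069 mutant barcodes. Its medians were 797.5 UMIs and 73.0% mitochondrial UMIs per barcode.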

How the results depend on the processing

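The settings without cluster 6, without condensate core gene cells, with cluster 15 only, with shared dermal clusters weighted alike, without the top 8% of doublet scores and with 5000 UMIs were chosen after seeing the data; the others were planned. No paired analysis was possible because each genotype had 1 library. Over 19 list medians that lay at least 1.5-fold from even, 236 of 243 alternative values kept their direction, as did 1932 of 1943 for 177 named genes. This tally is a weak check. The scaling settings moved all log2 ratios by 0.07 or less, and the named genes were picked for large ratios. The dermal Wnt target median ranged from -0.75 to -0.53, the Hedgehog median from -3.40 to -2.42, and the epidermal Wnt target median from -1.86 to -0.96. Except where a sentence says otherwise, the cause of each value below was not tested. The 185 epidermal cells of the mutant library limit the precision of epidermal values.

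Dermal G2M genes had a median of -0.69 in thinned cells, a setting that also leaves out shallow cells, and -0.73 without cluster 6. Dermal condensate genes had 0.10 without cluster 6 and 0.057 without cells with 2 or more core genes, a setting that by construction removes cells with these genes. With shared dermal clusters weighted alike, G2M genes had 0.10, condensate genes 0.0057, the cartilage gene Hapln1 -0.12 and dermal Wls -0.13. Dermal muscle markers had 0.24 for members with 100 or more UMIs. Epidermal G2M genes had 0.16 with median-of-ratios scaling, 0.14 without the top 50 genes, -0.049 in thinned cells, 0.16 in cells with 1000 or more genes and under 5% mitochondrial UMIs, 0.16 without doublet calls and 0.18 without the top 8% of doublet scores. Epidermal Wls had -4.75 in thinned cells, -5.17 without doublet calls and -5.79 without the top 8%. Bbc3 had 0.25 in thinned cells. Epidermal muscle markers had -3.15 without doublet calls, from 1 measured gene, and -0.37 with 1000 variable genes. Actc1 had -3.15, -2.11 without the top 8%, and -0.032 with 1000 variable genes. In cluster 15 only, placode genes had -0.76, Eda and NF-kB targets 0.30, Wnt10b 0.29, Msx2 0.72, Ltb 0.34, Krt1 -0.20, Cldn6 0.35 and Bbc3 0.58, where the wildtype-only cluster 18 is left out by construction.

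Differences in shares (mutant minus wildtype, in points) moved with their definitions. Dermal condensate cells differed by -7.37 with at least 2 genes, -2.75 with at least 4 and -5.30 unthinned. Wnt-active cells differed by -25.2, -21.2 and -20.2 under the same settings and by -20.7 at 5000 UMIs. Cycling cells were so named for UMIs of at least 5 G2M genes, which most cells of every class compared had. Their share differed by -24.1 with at least 10 genes, -16.3 at 5000 UMIs and 1.94 unthinned, where mutant cells were deeper and shallow cells were kept. Placode cells differed by -42.7 with at least 2 genes, -27.8 with at least 4 and -40.8 unthinned. Among cells with 1000 or more genes and under 5% mitochondrial UMIs, the authors' dermal share differed by 0.49 and the erythroid share by 0.52, a filter that removes debris and most erythroid cells.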

Other observations

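The comparisons with dermal levels and of condensate cells with other dermal cells, the equal weighting of clusters, and the tests of explanations for 3 patterns, were chosen after the results were seen; the medians of Wnt targets and G2M genes per class were planned. Wnt targets also had negative medians in several cell classes other than dermis and epidermis. In erythroid cells their median was 0.21 over 7 measured members, 1 higher and 1 lower, against a random-list median of 0.46 (percentile 12.4). In Schwann or neural crest cells, whose wildtype levels of these genes lay at 96.3% of the dermal level (median over members), 7 of 13 members were lower and 1 was higher, with a median log2 ratio of -0.71. Wif1, the secreted Wnt inhibitor, was at -3.18 there and Axin2, the feedback inhibitor of the pathway, at -0.81 (-1.11 to -0.51). The share of these cells with a UMI of at least 3 Wnt target genes was 30.5% in wildtype and 12.1% in the mutant library. Medians were -1.36 in macrophages, -0.93 in muscle, -0.70 in mural and -0.42 in mast or other myeloid cells. In wildtype macrophages the members lay at 16.7% of the dermal level, near the 19.2% at which the dermal collagen gene Col1a1 was found there. In wildtype mural cells they lay at 31.1% against 25.4% for Col1a1. In the mutant library the Col1a1 share was lower, at 6.56% in macrophages and 15.8% in mural cells. Less free dermal RNA there would also lower the Wnt target members, so free dermal RNA stays open for both classes. In wildtype muscle the members lay at 29.2% and in mast or other myeloid cells at 9.84%, above the Col1a1 share of either library.

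In wildtype dermis, UMIs of at least 5 G2M genes were found in 73.2% of 164 cells with 3 or more condensate core genes (65.7 to 79.8%) and in 94.6% of 3671 cells with 0 or 1 (93.8 to 95.3%), a difference that was not tested. Among the 10 highest dermal genes, Tbc1d8b, Trpc5 and A730046J19Rik lie on chromosome X, starting at 139684996, 144381671 and 144153695. Tbc1d8b was also higher in Schwann cells (log2 ratio 2.82, 1.16 to 5.17) and in the epidermis (2.42, 1.27 to 3.70). Gm10503 had 0 wildtype UMIs in muscle and macrophages and 41 and 54 in the mutant library. Among sex-linked genes over all cells, the Y-linked Ddx3y was at 58.9 and 56.2 CPM in wildtype and mutant, Eif2s3y at 55.4 and 58.1, Kdm5d at 13.3 and 12.6 and Uty at 12.9 and 14.7, while Xist, the X-inactivation RNA, was at 1.21 and 0.194 and Tsix at 0.258 and 0.219.

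With the 6 dermal clusters shared by both libraries weighted alike, FGF response genes had 3 of 8 members lower (median -0.07), BMP response genes 2 of 9 lower (median -0.36), Hedgehog targets 4 of 4 lower (median -2.42) and dissociation stress genes 3 of 14 lower (median -0.29).

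The lower Wnt targets of the mutant dermis (median -0.72) were weighed against 2 technical explanations. With the 6 dermal clusters that held cells of both libraries weighted alike, the median was -0.53. Of the 15 members, 7 were lower, against 11 over all cells. So a different mix of these clusters may account for part of the lower median but not for the whole. A different mix of cells within them stays open, since the weighting cannot see it. At Leiden resolution 1.0, 1 dermal cluster held 736 wildtype cells and 1 mutant cell. Clusters of 924 and 205 wildtype cells, mostly on the authors' dermal list, held no mutant cell at that resolution. RNA of epidermal cells in dermal droplets, scaled by Krt14, would make up 0.0489% of the wildtype level of the lower members (median), too little to account for the lower Wnt targets. A library-wide effect was not weighed and stays open. Medians of these genes were also negative in Schwann or neural crest cells (-0.71) and mural cells (-0.70). In erythroid cells the median was 0.21, below the random-list median of 0.46 (percentile 12.4). Genotype stays open and untested, since each genotype had 1 library.

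The lower G2M genes of the mutant dermis (median -0.51) were compared with the other classes. In 1 of 7 other classes, the endothelium (-0.43), the median was as low as the upper end of the dermal interval, which argues against a library-wide effect on cycling genes as the whole cause. Erythroid cells were left out of these 7, with a median of 0.15 (8 of 34 genes higher, 3 lower). Expression-matched random lists had a median of 0.43 there (percentile 0.69), so G2M genes were low against them in erythroid cells too. A smaller library-wide part stays open, since medians were below 0 in macrophages (-0.30), mural (-0.25), mast or other myeloid (-0.14) and Schwann or neural crest cells (-0.09) too, with intervals that excluded 0, but not in muscle (-0.03, -0.07 to 0.04) or epidermis (0.09). With the shared dermal clusters weighted alike the median was 0.10 (0.0997) with 1 of 50 genes lower, but 28 of the 50 genes helped to build those clusters, so a different mix of dermal clusters and a difference in cycling within them cannot be told apart. A difference between genotypes stays open as well.

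Gm10320 (chromosome 13, 98489348 to 98492001) was 132-fold lower in the mutant dermis. In the 5 other classes compared, the highest log2 ratio was -7.22, so a candidate explanation is a genetic difference between the pooled embryos or reads placed on a similar copy of the gene. Dermal RNA in other droplets would need low levels there, and the lowest wildtype level of the 5 was 41.0% of the dermal level, which argues against it. An effect of the Wls genotype in every class stays open, since the genotype and the embryos' background go together here, and so do both for Gm10503 and Tbc1d8b, which were higher in every class compared.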
